A study of Mus musculus with 16 samples.

How the data were processed

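Liver RNA was extracted with TRIzol and sequenced as poly(A) libraries made with the NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name the GRCm39 build, STAR and Salmon, without versions or roles; the annotation, the counting step and the handling of strand are not given in the sources used here. The deposited table holds estimated counts for 13006 genes in 16 libraries, and every value is a whole number. Its smallest values show that these estimated counts, as deposited by the authors, are not raw reads: among genes listed at 0 in at least 1 library, the median smallest nonzero value was 101.5 for genes under 150 bp of exon length and 1 for genes over 4000 bp, as for values rescaled by gene length. That check first used genes at 0 in at least 3 libraries, of which only 78.8% had an exon length, and was widened to at least 1 library (82.9% of 730 genes) after that coverage was seen. The values were tested as counts without further rounding, so floors are approximate and cover counting error only. Gene symbols came from the GENCODE mouse M21 annotation, which is for an earlier build, and matched 12692 identifiers; no coordinates are given, for lack of an annotation of the build used.

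Groups and replicate numbers came from the sample titles, with 4 libraries in each of 4 groups, and doses and days from the labels: ethinylestradiol at 10 mg/kg by injection for 7 days, and MI763F at 2.5 mg/kg by gavage for 6 days from day 2. The labels do not say whether mice without MI763F received its oral vehicle. A further MI763F dose that the labels mention was not analysed here. Totals ran from 14115384 to 21473227 estimated counts. At most 3.24% of genes held the same value in any pair of libraries.

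The tests, the gene lists and the rule for naming genes were fixed before the data were examined. Counts were filtered with filterByExpr, which left 12918 genes, scaled with TMM factors and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit, robust, 1 coefficient per group, all 16 libraries, 12 residual degrees of freedom). Quasi-likelihood tests were run for 5 contrasts, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05; standard errors are the fold change divided by the square root of the test statistic. CPM values use the TMM factors. The biological coefficient of variation was 0.284. For a group at 0 counts in every library, folds were set against a floor of 3 counts per library.

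The 25 lists cover CAR and PXR targets, bile acid synthesis, transport and receptors, male- and female-predominant genes, cholesterol, fatty acid synthesis and oxidation, glucose, acute phase, proliferation, oxidative and endoplasmic reticulum stress, pericentral and periportal genes, secreted proteins, clock genes, and markers of cholangiocytes, macrophages, stellate, endothelial, lymphoid and neutrophil, red and pancreatic acinar cells. The 24 with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 120 tests. Of the 72 calls, 3 held with an estimated correlation: secreted proteins in EV vs CV and in EM vs CV, and CAR and PXR targets in EM vs EV.

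Named genes were the 6 largest rises and 6 largest falls of each of the comparisons EV vs CV, CM vs CV and EM vs EV (4 and 4 for EM vs CV and the interaction) among called genes with a mean log2 CPM of at least 1 and groups that do not overlap, up to 4 members of each list by p, and a fixed set of bile acid, CAR and PXR genes. The genes printed are a part of those the rule names, picked after their values were seen, and some named by the rule are not reported here. The share of EE changes of opposite sign was recomputed with the EV libraries divided between the comparisons. It was also computed in 20 simulations with no ligand effect, in which each gene was drawn independently.

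The alternatives to these settings were RLE factors, no low count filter, a filter of 1 CPM in 8 libraries, DESeq2 1.42.0, only the groups compared, the replicate number as a block, each library left out, larger EE changes only, and estimated correlation and fry for the lists. Library totals without composition factors and limma with a trend (prior count 2) were added after the data were seen.

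The procedure was tested on simulated counts with 200 changed genes per comparison. Changes of 1.5-fold, 2-fold and 4-fold were recovered in 29.9%, 58.2% and 87.9% of cases for EV vs CV, 19.4%, 59.7% and 90.9% for CM vs CV, 25.4%, 65.7% and 89.4% for EM vs EV, 14.9%, 61.2% and 89.4% for EM vs CV, and 4.48%, 34.3% and 78.8% for the interaction. In each comparison the changed list was called and 0 of 20 random lists were. Each gene was drawn independently here too. These lists therefore cannot show how often the preset correlation gives false calls for genes that move together. A simulated return of 50% was found as 48.8%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.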

Results

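Liver messenger RNA was measured by poly(A) RNA sequencing in mice labelled Humanized PXR-CAR-CYP3A4/3A7, which carry human versions of the xenobiotic receptors PXR and CAR and of drug-metabolising enzymes. The 16 libraries form 4 groups of 4. CV mice received the propylene glycol vehicle, and EV mice received ethinylestradiol (EE), a synthetic estrogen that induces cholestasis, at 10 mg/kg for 7 days. CM and EM mice received MI763F, a CAR ligand known by its code name, at 2.5 mg/kg for 6 days from day 2, without EE and with EE respectively. The comparisons ask what EE changed, what the ligand changed without and with EE, and whether the ligand moved the EE changes back. Estimated counts summed to between 14115384 and 21473227 per library, and 12918 of 13006 genes were tested. Nothing in the labels ties each library to its own animal, so the p-values measure the spread between these samples.

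EE status accounted for the first principal component, which held 48.3% of the variance against 6.17% for the second. All 8 libraries with EE lay above 0 on the first component and all 8 without EE lay below it. Within the EE libraries EM replicate 1 (62.6) lay nearest to the EV libraries (66.7 to 75.4), while the other EM libraries lay between 37.1 and 46.7. CM replicate 2 stood apart from its group on the second component, at -58.9 against -16.1 to -7.98 for the other CM libraries. The scaling factors were 0.833 to 0.91 without EE and 1.1 to 1.23 with EE.

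**Figure D1:**
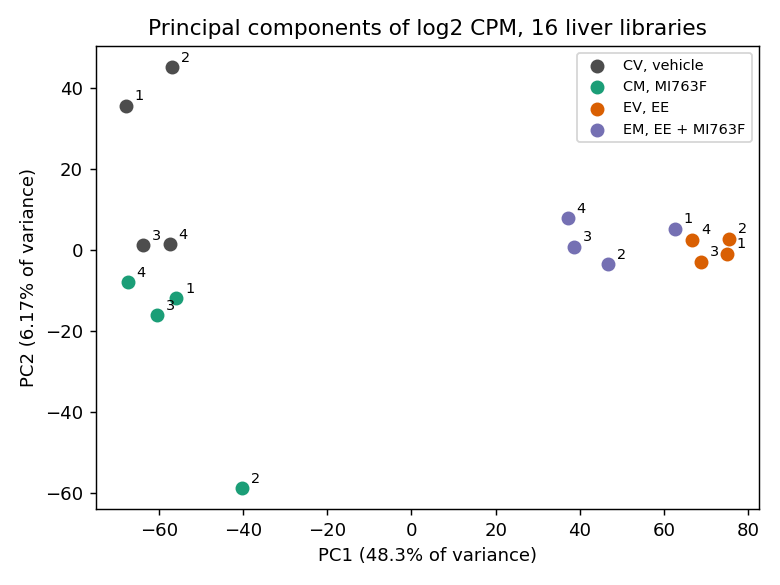
Principal components of log2 CPM for the 16 libraries, with the first component (48.3% of the variance) on the x axis and the second (6.17%) on the y axis; each point is a library, coloured by group and numbered by replicate. The EV libraries lie between 66.7 and 75.4 on the first component, and EM replicate 1 lies nearest to them at 62.6.

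With EE alone, bile acid genes changed in both directions. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 62.4 ± 13 CPM in CV to 5.71 ± 6 in EV (SD, n = 4; log2 fold change -3.47 ± 0.78 SE, adjusted p = 0.00218). Cyp8b1, which is needed for cholic acid, fell from 102 ± 29 to 1.37 ± 0.71 CPM (-6.23 ± 0.67, adjusted p = 4.87e-06). Cyp7b1, an oxysterol hydroxylase, rose from 18.7 ± 4.3 to 1340 ± 100 CPM (6.17 ± 0.19, adjusted p = 8.77e-12). The basolateral bile acid uptake carrier Slc10a1 fell from 669 ± 48 to 124 ± 12 CPM (-2.44 ± 0.18, adjusted p = 6.58e-08), and the bile salt export pump Abcb11 fell from 319 ± 74 to 128 ± 18 CPM (-1.32 ± 0.18, adjusted p = 1.86e-05). In all, 6513 of 12918 genes changed, 3291 up and 3222 down, and 2827 of them by at least 2-fold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With library totals in place of the composition factors, 8377 genes changed, 84.1% of them upward against 50.5% here, because the median of all genes then shifted by 0.49 on the log2 scale.

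**Figure D2:**
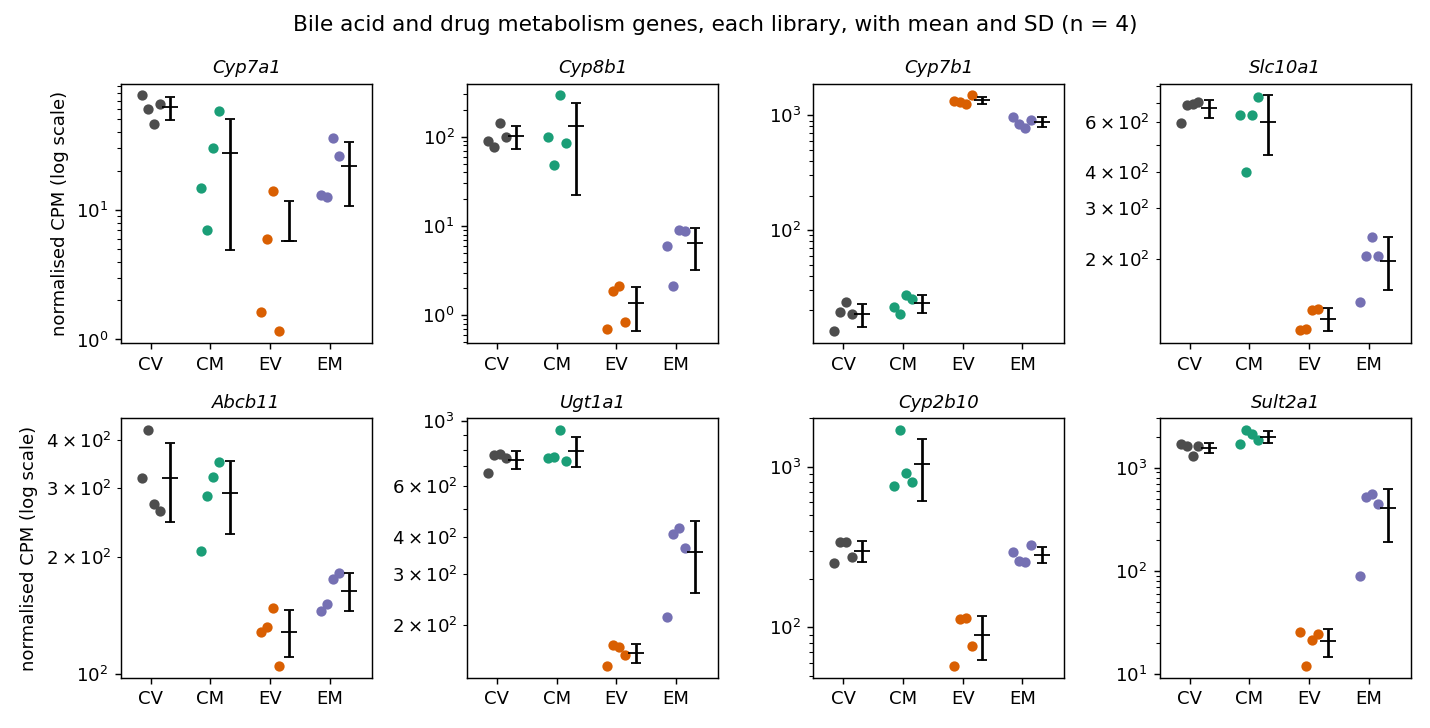
Normalised CPM (log axis) of 8 bile acid and drug metabolism genes in each library of the 4 groups; coloured points are libraries and the black mark and bar beside them are the mean and SD (n = 4). No lower bar is drawn for Cyp7a1 in EV, whose SD exceeds its mean. Cyp7b1 averages 18.7 CPM in CV and 1340 in EV, and Sult2a1 averages 20.9 CPM in EV and 404 in EM.

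Among bile acid synthesis and conjugation genes, 13 of 17 measured members fell with EE, Slc27a5 (-2.38) and Cyp39a1 (-3.71) among them, and Cyp7b1 rose. The list was lower (camera adjusted p = 0.0013, or adjusted p = 0.36 with an estimated correlation). Of 13 transporters, 10 fell, including Abcc2 (-1.47 ± 0.13) and Slco1a4 (-2.28 ± 0.22), and 2 rose, including Abcg2 (1.21 ± 0.15). The list was lower (adjusted p = 0.0022, or adjusted p = 0.32 with an estimated correlation). The falls of Abcc3 (-0.43 ± 0.12) and Abcb4 (-0.48 ± 0.13) rest on the scaling, since library totals gave 0.05 and 0.01. The calls of Cyp27a1 (-0.79), Slco1b2 (-0.72), the bile acid receptor Nr1h4 (-0.74) and Per1 (-0.86) were lost with library totals. Of 15 receptors, 11 fell, among them Rxra (-0.73), Nr5a2 (-1.04) and Klb (-1.46). The list was lower (adjusted p = 0.00074, or adjusted p = 0.15 with an estimated correlation). With library totals 5 receptors fell and 2 rose, 6 transporters fell and 2 rose, and 10 bile acid synthesis genes fell and 4 rose. Nr0b2 (-0.05 ± 0.37) and the estrogen receptor Esr1 (-0.34 ± 0.15) did not pass the test.

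Of 31 CAR and PXR target genes, 22 fell with EE and 2 rose. Cyp2c37 fell by 3.93 and Ces2a by 2.01 on the log2 scale. Ugt1a1, the bilirubin glucuronosyltransferase, fell from 738 ± 51 to 161 ± 12 CPM (-2.20 ± 0.17, adjusted p = 1.22e-07), and Cyp2b10, the classical CAR target, from 301 ± 46 to 90.1 ± 27 CPM (-1.74 ± 0.26, adjusted p = 4.94e-05). The list was lower (adjusted p = 5.3e-10, or adjusted p = 0.15 with an estimated correlation). Mouse Nr1i3 (-1.32 ± 0.21) fell and mouse Nr1i2 (-0.10 ± 0.094) did not pass. Both are uncertain in animals that carry human counterparts, since reads can be shared. The data also hold 3 entries with human-format identifiers, which the mouse name table does not pair with symbols. Of these, ENSG00000143257 fell from 214 ± 31 to 67.6 ± 7.4 CPM (-1.66 ± 0.21, adjusted p = 1.29e-05). ENSG00000160868 fell from 1240 ± 590 to 529 ± 200 CPM (-1.23 ± 0.35, adjusted p = 0.0086), a call lost with library totals. ENSG00000144852 went from 61.1 ± 5.7 to 52.7 ± 5.8 CPM and did not pass (adjusted p = 0.0761).

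Genes with a known sex bias in mouse liver moved apart. Of 14 male-predominant genes 12 rose, including Mup20 (3.69 ± 0.37) and Cyp4a12a (5.97 ± 0.85; adjusted p of the list = 1.3e-06, or adjusted p = 0.14 with an estimated correlation). Of 19 female-predominant genes 14 fell and 2 rose, with Fmo2 (-3.73 ± 0.29) and Acot4 (-2.29 ± 0.19) among the falls (adjusted p = 1.1e-08, or adjusted p = 0.083 with an estimated correlation). The exonuclease gene Trex2, at 0 in every CV library, averaged 61.9 ± 7.5 CPM in EV, at least 300-fold higher against a floor of 3 counts per library. The keratins Krt4 (12.39 ± 0.45) and Krt79 (9.97 ± 0.31) rose. Krt4 lay between 0 and 0.229 CPM in the CV libraries, so its fold rests on few counts and is approximate. The same holds for Cyp4a12a, at 0.127 ± 0.13 CPM in CV. Rgs16 (-8.41 ± 0.61), Slc22a26 (-8.09 ± 0.41) and Hsd17b6 (-7.82 ± 0.52) were among the largest falls by the naming rule. Members of the Mup, Cyp2b, Cyp2c, Cyp3a, Cyp4a12 and Sult2a families resemble their neighbours closely, so the division of reads among them is uncertain.

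Metabolic lists other than that of fatty acid oxidation were lower with EE. All but 5 of 24 cholesterol genes fell, including Tm7sf2 (-3.14) and Ebp (-1.26; adjusted p = 1e-04, or adjusted p = 0.53 with an estimated correlation). Of the fatty acid and triglyceride synthesis genes 14 of 18 fell, including Fads1 (-2.58) and Mlxipl (-1.39; adjusted p = 2.3e-05, or adjusted p = 0.37). Glucose genes gave 8 falls, such as Slc2a2 (-2.70), and 2 rises among 12 (adjusted p = 0.0056, or adjusted p = 0.28 with an estimated correlation). Fatty acid oxidation genes split into 4 rises, such as Ehhadh (2.34), and 11 falls, such as Acaa2 (-0.91), among 22. The list did not pass (adjusted p = 0.37), and its median (-0.29) and mean (0.05) differ in sign. With library totals 7 of its genes rose and 4 fell, and the median was 0.19. With library totals 11 cholesterol genes fell and 2 rose, and 9 fatty acid and triglyceride synthesis genes fell and 1 rose. Pericentral genes fell in 9 of 11 cases, with Cyp2e1 at -3.84 and Glul at -1.37 (adjusted p = 7.1e-06, or adjusted p = 0.18 with an estimated correlation). Periportal genes gave 6 falls, including Gls2 (-2.49), and 3 rises among 12 (adjusted p = 0.0065, or adjusted p = 0.37). Hepatocyte secreted proteins fell in 11 of 12 cases, with Serpinc1 at -1.81 and Apoa1 at -2.88 (adjusted p = 2.8e-10), and this call held with an estimated correlation (adjusted p = 0.031).

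Proliferation genes and markers of other cell types rose in the same libraries. Some proliferation genes were low in CV, such as Mki67 (0.192 ± 0.05 CPM) and Top2a (0.453 ± 0.36 CPM), so their folds are approximate. All 21 proliferation genes rose, including Mki67 (4.52 ± 0.43) and Top2a (5.08 ± 0.52; adjusted p = 7.3e-08, or adjusted p = 0.32 with an estimated correlation). Macrophage markers rose in 11 of 13 cases, with Clec4f at 1.93 and Csf1r at 2.74 (adjusted p = 6.3e-08, or adjusted p = 0.29). Lymphocyte and neutrophil markers rose in 6 of 9, including Ptprc (2.56; adjusted p = 0.0067, or adjusted p = 0.37). All 5 erythrocyte markers rose, including Hbb-bt (1.32; adjusted p = 0.048, or adjusted p = 0.53). Both list calls were lost with library totals (adjusted p = 0.1 and 0.13). Sinusoidal endothelial markers rose in 8 of 11, including Cdh5 (1.83; adjusted p = 0.006, or adjusted p = 0.53 with an estimated correlation). The lists of stellate (6 up, 1 down of 12; adjusted p = 0.22), cholangiocyte (2 up of 5; 0.24), acute phase (4 up of 21; 0.36), endoplasmic reticulum stress (4 up of 12; 0.13), oxidative stress (5 up, 2 down of 11; 0.7) and clock genes (1 up, 8 down of 13; 0.15) did not pass. Among their members, Col1a1 (1.48), Sox9 (3.67), Saa3 (2.67), Hspa5 (1.19) and Srxn1 (1.38) rose and Nr1d1 (-2.09) fell. With library totals the clock list passed as lower (camera adjusted p = 0.013, with 4 up and 7 down). Under the same scaling 8 acute phase, 11 endoplasmic reticulum stress and 8 oxidative stress genes rose, and 2 oxidative stress genes fell. Pancreatic acinar markers had too few measured members for a list test; Cela2a rose by 2.65 ± 0.71 and Cela1 (-0.22 ± 0.28) did not pass. Adjusted over the list alone, the counts were the same except for cholesterol genes (21 down), secreted proteins (12 down), endothelial markers (9 up), stellate markers (2 down) and acute phase genes (3 up).

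**Figure D3:**
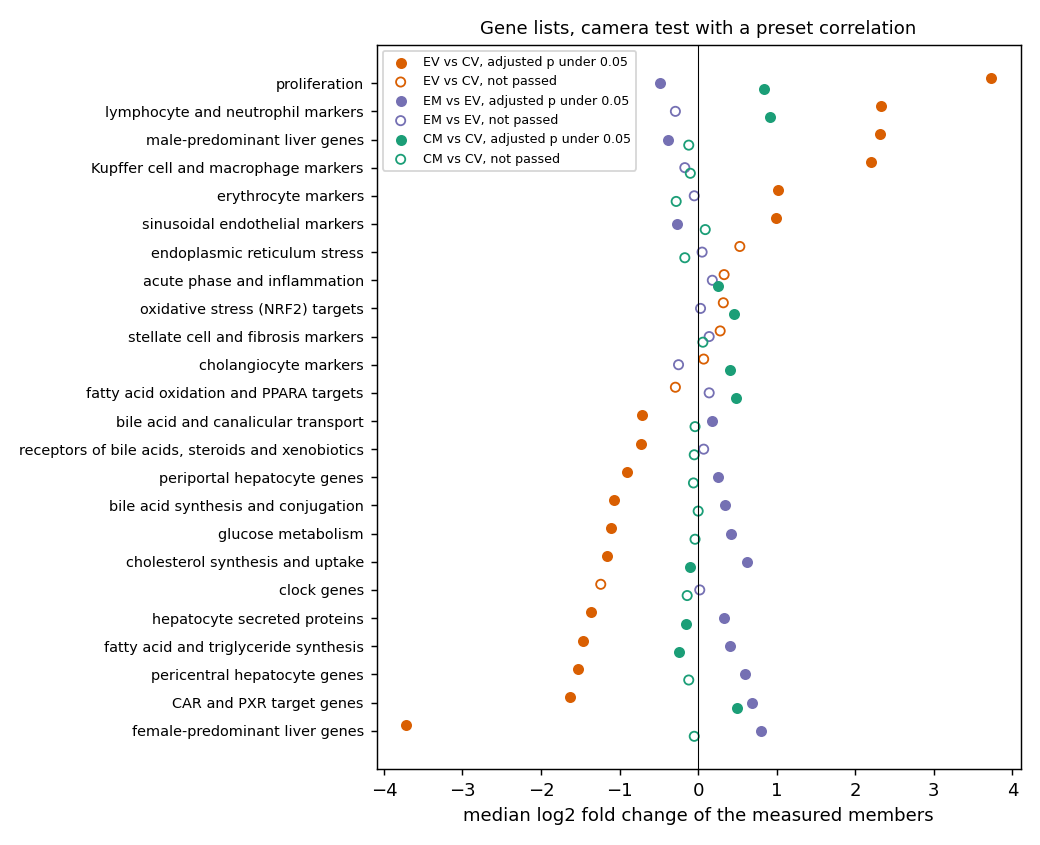
Median log2 fold change (x axis) of the measured members of each tested gene list (y axis) for EE (EV vs CV), MI763F with EE (EM vs EV) and MI763F without EE (CM vs CV); filled points passed the camera test with a preset correlation and open points did not. The hepatocyte secreted list has a median of -1.36 for EV vs CV and 0.33 for EM vs EV.

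Without EE, a small set of genes was higher in mice given the ligand. Neither chance nor handling before sampling could be excluded for this set, as described below. Cyp2b10 rose from 301 ± 46 CPM in CV to 1050 ± 440 in CM (SD, n = 4; log2 fold change 1.80 ± 0.26 SE, adjusted p = 0.00953), and Cyp2c29, another CAR target, from 3820 ± 590 to 10400 ± 3500 CPM (1.45 ± 0.2, adjusted p = 0.00756). St5 rose from 12.9 ± 2.3 to 33.3 ± 3.9 CPM (1.37 ± 0.13, adjusted p = 0.000341). The stress cytokine Gdf15 (1.79 ± 0.31, adjusted p = 0.0469), the phosphatase gene Dusp1 (1.54 ± 0.26, adjusted p = 0.0454) and the lipolysis inhibitor G0s2 (1.26 ± 0.22, adjusted p = 0.0469) also rose. ENSG00000160868 averaged 3160 ± 1000 CPM in CM against 1240 ± 590 in CV and did not pass (adjusted p = 0.182). Nor did Cyp7a1 at 27.5 ± 23 against 62.4 ± 13 CPM (adjusted p = 0.606), ENSG00000143257 (adjusted p = 0.947) or ENSG00000144852 (adjusted p = 0.622). In all 12 genes rose and 0 fell by edgeR's quasi-likelihood test, with 1362 genes at an unadjusted p under 0.05. DESeq2 called 238 (168 up, 70 down), and a fit to these groups alone called 2. Leaving out CV replicate 1 left 4 genes and ended the calls of Cyp2b10 (adjusted p = 0.0667) and Cyp2c29 (adjusted p = 0.0515). The count was 7 without CM replicate 2 and 39 without CM replicate 4. The calls of Gdf15, Dusp1 and G0s2 were each lost without any of several CV or CM libraries, CM replicates 2 and 3 included (highest adjusted p = 0.162, 0.143 and 0.173), and with library totals.

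Of the 31 CAR and PXR targets, the 2 that rose over all genes became 15 when adjusted over the list alone, and the list was higher (camera adjusted p = 1.4e-13, or adjusted p = 0.083 with an estimated correlation). Fatty acid oxidation and PPARA targets were higher as a list (0 of 22 called, 8 up adjusted over the list alone; adjusted p = 4e-11, or adjusted p = 0.15), with Pdk4 at 2.10 ± 0.62 and Cyp4a10 at 0.90 ± 0.3, neither called. So were proliferation (3 of 21 adjusted over the list alone; adjusted p = 1.9e-06, or adjusted p = 0.36), oxidative stress (4 of 11; 1.9e-06, or adjusted p = 0.14), lymphocyte and neutrophil (0 of 9; 0.00056, or adjusted p = 0.29), cholangiocyte (0 of 5; 0.022, or adjusted p = 0.29) and acute phase genes (0 of 21; 0.034, or adjusted p = 0.64). Fatty acid and triglyceride synthesis (0 of 18; adjusted p = 0.00021, or adjusted p = 0.38 with an estimated correlation), cholesterol (0 of 24; 0.029, or adjusted p = 0.75) and secreted protein genes (0 of 12; 0.046, or adjusted p = 0.37) were lower as lists. The other 14 lists did not pass. Some proliferation genes, such as Mki67 (0.192 ± 0.05 CPM in CV, 0.362 ± 0.065 in CM), were low, so their folds rest on few counts.

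In EE mice, the ligand raised sulfotransferase and CAR target genes that EE had lowered. Sult2a1, which sulfates bile acids and steroids, rose from 20.9 ± 6.2 CPM in EV to 404 ± 210 in EM (SD, n = 4; log2 fold change 4.27 ± 0.45 SE, adjusted p = 0.000314), and Sult2a5 from 8.12 ± 0.81 to 72.2 ± 24 CPM (3.15 ± 0.21, adjusted p = 2.91e-06). Cyp2b10 rose from 90.1 ± 27 to 284 ± 32 CPM (1.66 ± 0.26, adjusted p = 0.00549), Ugt1a1 from 161 ± 12 to 356 ± 99 CPM (1.15 ± 0.17, adjusted p = 0.00417) and Cyp2c37 by 2.12 ± 0.23 (adjusted p = 0.000314). Mllt3 (-1.38 ± 0.21, adjusted p = 0.00546) fell, as did Krt4, from 406 ± 110 to 202 ± 58 CPM (-1.01 ± 0.23, adjusted p = 0.0416). The bile acid genes Cyp7a1 (22 ± 11 CPM in EM, adjusted p = 0.263), Cyp8b1 (6.42 ± 3.2 CPM, adjusted p = 0.111), Cyp7b1 (875 ± 84 CPM, adjusted p = 0.051), Slc10a1 (197 ± 41 CPM, adjusted p = 0.0647) and Abcb11 (163 ± 18 CPM, adjusted p = 0.43) did not pass. ENSG00000160868 rose from 529 ± 200 to 1900 ± 390 CPM (1.85 ± 0.36, adjusted p = 0.0207), while ENSG00000143257 (adjusted p = 0.584) and ENSG00000144852 (adjusted p = 0.993) did not pass.

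In all, 218 genes changed, 195 up and 23 down (edgeR's quasi-likelihood test; 1642 at an unadjusted p under 0.05). DESeq2 called 487 up and 99 down. With library totals 127 changed, 59.1% upward against 89.4% here, and the median of all genes shifted by -0.11. The count rested on single libraries: it was 41, 36, 127 and 93 without EV replicates 1 to 4, and 445, 93, 68 and 64 without EM replicates 1 to 4. Sult2a1, Sult2a5, Slc22a26, Cyp2b9, Cyp2b10, Cyp2c37, Cyp2c50, Ugt1a1 and Mllt3 were called with each of these libraries left out. The other 22 named calls were each lost without at least 1 library, at highest adjusted p between 0.0522 and 0.183. Of these, Krt4, Cyp39a1, Cyp2e1, Glul, Fads1, Serpinc1, Apoa2 and ENSG00000160868 were lost without EV replicate 1 and without EV replicate 2.

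As lists, CAR and PXR targets were higher (8 of 31 rose, 16 adjusted over the list alone; camera adjusted p = 1.1e-23), and this call held with an estimated correlation (adjusted p = 0.036). Cholesterol genes were higher (0 of 24; adjusted p = 2.9e-09, or adjusted p = 0.37 with an estimated correlation), as were female-predominant genes (4 of 19 rose, including Cyp2b9 at 2.84, and 5 adjusted over the list alone; 1.3e-08, or adjusted p = 0.083) and bile acid synthesis genes (3 of 17 rose, including Cyp39a1 at 2.00, and 9 up with 1 down adjusted over the list alone; 1.3e-07, or adjusted p = 0.15). Pericentral (2 of 11 rose, Cyp2e1 at 1.21 and Glul at 0.60, and 6 adjusted over the list alone; 1.3e-06, or adjusted p = 0.15), secreted protein (2 of 12 rose, Apoa2 at 0.69 and Serpinc1 at 0.50, and 5; 3.5e-06, or adjusted p = 0.083), fatty acid synthesis (1 of 18 rose, Fads1 at 0.90, and 2; 1e-04, or adjusted p = 0.37), glucose (0 of 12, and 3; 0.00033, or adjusted p = 0.15), periportal (2 of 12, and 3; 0.0066, or adjusted p = 0.37) and transport genes (0 of 13, and 1; 0.024, or adjusted p = 0.41) were higher as lists. Proliferation (0 of 21; adjusted p = 4.3e-05, or adjusted p = 0.37 with an estimated correlation), male-predominant (0 of 14, 1 down adjusted over the list alone; 0.0027, or adjusted p = 0.29) and endothelial genes (0 of 11; 0.015, or adjusted p = 0.55) were lower as lists. The other 11 lists did not pass, macrophage markers among them (adjusted p = 0.15). Cyp2b9 and Cyp2b13, among the 4 female-predominant genes that rose, are also members of the CAR and PXR list. The results of these lists are therefore not independent. With library totals, 11 of the 31 named calls were lost, those of Cyp2e1, Glul, Fads1 and Serpinc1 among them. The rises then numbered 5 of CAR and PXR targets, 1 of bile acid synthesis and 1 of secreted protein genes, and 0 of pericentral, periportal and fatty acid synthesis genes. Of the bile acid synthesis genes 1 then fell.

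Mice given both treatments differed from vehicle in bile acid genes. Cyp7b1 was at 875 ± 84 CPM in EM against 18.7 ± 4.3 in CV (SD, n = 4; log2 fold change 5.55 ± 0.18 SE, adjusted p = 3.08e-11), Slc10a1 at 197 ± 41 against 669 ± 48 CPM (-1.76 ± 0.17, adjusted p = 2.96e-06) and Cyp8b1 at 6.42 ± 3.2 against 102 ± 29 CPM (-3.98 ± 0.58, adjusted p = 0.000113). Ugt1a1 (-1.05 ± 0.17, adjusted p = 0.000153) and Abcb11 (-0.97 ± 0.17, adjusted p = 0.000441) were also lower. Cyp2b10 differed from vehicle by -0.08 ± 0.25 (adjusted p = 0.823), Nr1h4 by -0.27 ± 0.13 (adjusted p = 0.112) and ENSG00000160868 by 0.61 ± 0.35 (adjusted p = 0.175). Cyp7a1 was at 22 ± 11 against 62.4 ± 13 CPM (adjusted p = 0.109), and none of these passed. Trex2 was at least 175-fold higher than in CV, Krt4 (11.38 ± 0.45) and Krt79 (9.42 ± 0.31) were higher, and Hsd17b6 (-7.03 ± 0.49) and Rgs16 (-6.07 ± 0.52) were lower. The fold of Krt4 again rests on few counts in CV. In all 5251 genes differed, 2668 up and 2583 down (edgeR's quasi-likelihood test). With library totals 6979 differed, 85.7% of them upward against 50.8% here. The secreted protein list was lower (12 of 12; camera adjusted p = 7.1e-10, or adjusted p = 0.031 with an estimated correlation), and macrophage markers were higher (11 of 13; 8.8e-10, or adjusted p = 0.26). Both counts were the same adjusted over the list alone. Of 24 lists, 6 were higher and 11 lower, and 7 did not pass. Lists of female-predominant genes (12 of 19 lower, 2 higher; adjusted p = 2.3e-08, or adjusted p = 0.083 with an estimated correlation) and CAR and PXR targets (17 of 31 lower, 2 higher; 1e-05, or adjusted p = 0.29) were among the lower ones. Proliferation genes (18 of 21 higher; 1.6e-07, or adjusted p = 0.36) and male-predominant genes (9 of 14 higher; 4.9e-07, or adjusted p = 0.14) were among the higher ones. Adjusted over the list alone, 12 female-predominant and 18 CAR and PXR genes were lower, and 19 proliferation and 11 male-predominant genes were higher. With library totals 6 CAR and PXR targets were higher and 15 lower.

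The change with the ligand differed between mice with and without EE for 17 genes, 13 with a higher and 4 with a lower change in EE mice. This is edgeR's quasi-likelihood test of the interaction, with 1759 genes at an unadjusted p under 0.05 and 462 called by DESeq2. The same contrast equals the EE change with the ligand minus that without it. A smaller EE change in mice given the ligand would thus give such a difference too, for genes and lists alike. The largest differences by the naming rule were those of Sult2a1 (3.91 ± 0.58, adjusted p = 0.0139), Slc22a26 (3.34 ± 0.49, adjusted p = 0.0122), Sult2a5 (2.89 ± 0.28, adjusted p = 0.000414) and Sult2a6 (2.63 ± 0.31, adjusted p = 0.00188). EE alone had lowered each of them (-6.21, -8.09, -5.5 and -4.69). Gm20075, which the rule skips, differed by -9.39 ± 0.95 (adjusted p = 0.00188), with ligand changes of 8.42 without EE and -0.97 with EE. St5 rose without EE and was at 23.4 ± 2.1 CPM in EM against 25 ± 2.4 in EV (interaction -1.46 ± 0.18, adjusted p = 0.00248). Ufm1 (-0.85 ± 0.15, adjusted p = 0.0452) was lost in 11 of 16 fits with a library left out, at up to 0.108. For Cyp2b10 the difference was -0.14 ± 0.35 (adjusted p = 0.897), for Ugt1a1 1.05 ± 0.23 (adjusted p = 0.0737), for Cyp7b1 -0.93 ± 0.22 (adjusted p = 0.077) and for ENSG00000160868 0.50 ± 0.49 (adjusted p = 0.701). The count was 26 without CV replicate 3, 95 without CM replicate 4, 10, 10 and 28 without EV replicates 1 to 3, and 208, 26 and 10 without EM replicates 1, 2 and 4.

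As lists, 15 of 24 differed in their response to the ligand with and without EE, 9 with a higher and 6 with a lower change in EE mice, and 0 of the 15 calls held with an estimated correlation. Cholesterol genes (median difference 0.71; camera adjusted p = 1.3e-08, or adjusted p = 0.37 with an estimated correlation), fatty acid synthesis genes (0.74; 2e-07, or adjusted p = 0.29) and pericentral genes (0.81; 0.00011, or adjusted p = 0.27) had a higher change with EE. Secreted protein genes (0.42; 3.6e-06, or adjusted p = 0.083) and female-predominant genes (0.80; 1.7e-05, or adjusted p = 0.15) did too. Proliferation genes (-1.28; 1e-09, or adjusted p = 0.26), lymphocyte and neutrophil markers (-1.03; 0.00042, or adjusted p = 0.29) and fatty acid oxidation genes (-0.32; 0.00043, or adjusted p = 0.41) had a lower change. Of the members of these 8 lists, 1 of the 19 female-predominant genes passed the test of the difference over all genes and 0 of the others. Adjusted over the list alone, 6 of 12 secreted protein, 5 of 11 pericentral, 4 of 18 fatty acid synthesis and 3 of 19 female-predominant genes had a higher change, and 1 female-predominant gene a lower one. Of 22 fatty acid oxidation genes 4 then had a lower and 1 a higher change. For CAR and PXR targets the median difference was 0.07 (adjusted p = 0.021, or adjusted p = 0.53) and -0.04 with library totals.

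Set against the EE changes, the ligand changes ran the other way. Of the 6513 EE-changed genes, 5673 (87.1%) had a ligand change of opposite sign in EE mice; 215 of these were called in the opposite direction and 0 in the same direction. The median gene moved back by 21.4% of its EE change on the log2 scale, 27.3% for genes lowered by EE and 16.9% for genes raised by it. Both comparisons use the EV libraries, so simulated libraries with no ligand effect also gave 56.4% of opposite sign on average (54.4% to 57.4% over 20 simulations). They gave 0.05 called genes on average. Each gene was drawn independently, so correlation between genes could widen that range. With the EV libraries divided between the comparisons, the share was 83.4% on average (81.1% to 85.5% over 6 divisions) and the median 19.3%, while the calls dropped to 29 on average (13 to 68). Genes lowered by EE and raised by the ligand numbered 192 (48.6 for independent lists), and genes raised by EE and lowered by the ligand 23 (5.86 for independent lists). Across genes, which are not independent replicates, Pearson's r of the fold changes was -0.54 (-0.173 simulated), with a covariance of -0.449 (-0.113 simulated). The 4 EM libraries taken singly gave 63.5%, 77.1%, 84.4% and 85.7%.

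**Figure D4:**
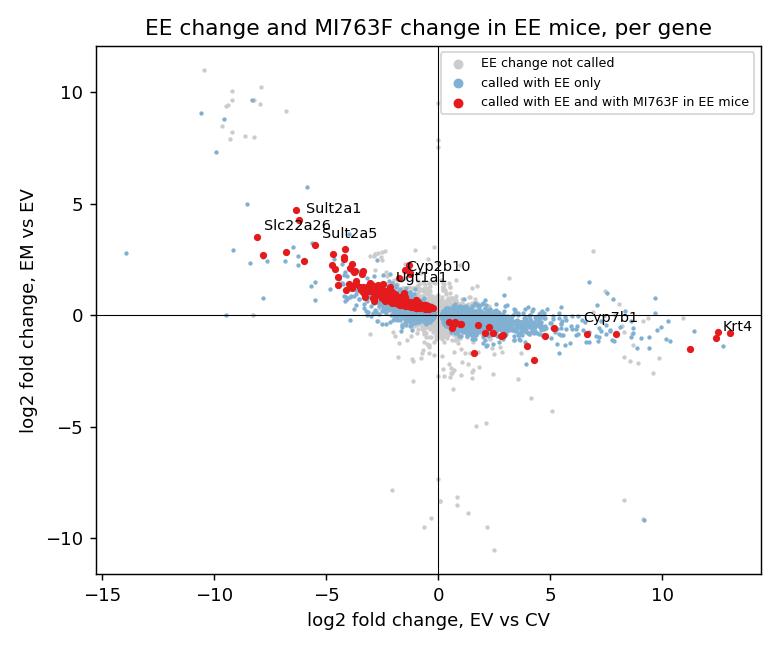
Log2 fold change of each tested gene with EE (EV vs CV, x axis) and with MI763F in EE mice (EM vs EV, y axis); red points are genes called in both comparisons, blue points those called with EE only. Both axes use the EV libraries, which alone tilts the cloud; of 6513 EE-changed genes 87.1% lie on opposite sides of 0.

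CAR and PXR targets were higher with the ligand without EE (median 0.50), a call lost with an estimated correlation (camera adjusted p = 0.083), and with EE (median 0.69), a call that held (adjusted p = 0.036). Across all genes, Pearson's r of the fold changes was -0.0283 and Spearman's rho -0.106. Only Cyp2b10 was raised in both, by 1.80 and 1.66, against 0.181 genes for independent lists (Fisher's exact p = 0.167). This count was 0 without CV replicate 1 (Fisher's exact p = 1), and 2 without CM replicate 2 (exact p = 0.00688) or EM replicate 2 (exact p = 0.00149). The exact p was also under 0.05 with EV replicate 1, 2 or 3 or EM replicate 3 or 4 left out (0.0157 to 0.0499).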

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

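The tests of a uniform weakening, cell shares, scaling and CM replicate 2 were chosen after the results were seen; the fits with the EV libraries divided and with 1 library left out were planned, and their use as tests of shared and single libraries was set after the results were seen. The immediate-early list was fixed after Dusp1 had been seen but before its own values, and the splits of the samples were planned. Among 96 groups of 4 values examined for 1 value far from the rest, 9 had one, where chance gives about 4.8; 8 of the 9 are given here. The gap to the nearest value over the range was 0.885 for the TMM factor of EM replicate 4 (1.1 against 1.12 to 1.13) and 0.841 for CM replicate 2 on the second principal component. Cyp2b10 was at 1690 CPM in CM replicate 2 against 764 to 920 (0.832), and Dusp1 at 48.6 in EM replicate 2 against 27.2 to 29.8 (0.878). In CV, Slc10a1 was at 597 CPM in replicate 1 against 685 to 702 (0.83), Slc22a26 at 200 in replicate 1 against 148 to 156 (0.852) and Sult2a1 at 1290 in replicate 3 against 1620 to 1680 (0.838). Ugt1a1 was at 932 CPM in CM replicate 3 against 728 to 757 (0.861).

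The effect of MI763F differed between mice with and without EE, by a test of the difference, for Sult2a1 (3.91), Slc22a26 (3.34), Sult2a5 (2.89), Sult2a6 (2.63), St5 (-1.46) and Ufm1 (-0.85). A smaller EE change in mice given the ligand would give such a difference too. Of 100 drawn splits of the samples, 4 gave at least the 17 genes of the real labels, the real one included, and the highest of the others gave 70. Most splits also mix EV with EM and so remove the ligand effect itself, which makes their low counts no test of a difference in that effect. The 3 drawn splits that keep the EV and EM libraries apart mix CV with CM and gave 57 to 70 genes. They keep the ligand effect with EE and mix the labels without EE, so a difference is built in. Neither kind of split tests chance for the count of 17, which therefore stays open.

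The ligand changes in EE mice ran opposite to the EE changes for 87.1% of EE-changed genes. The use of the EV libraries in both comparisons does not alone account for it, since the lowest share with these libraries divided was 81.1%. The highest simulated share was 57.4%, but the simulations drew each gene independently. Genes that move together could give a larger share by chance, so the simulated share sets no limit for chance. No single library accounts for it either, with a lowest share of 83.4% when 1 was left out. A uniformly weaker EE effect would move each gene back by the common 19.3%. Of 6513 EE-changed genes, 18 departed from that (edgeR, Benjamini-Hochberg), 14 of them with at least 20 counts in both CV and EV. Several of the 18 belong to the Sult2a and Cyp2c families, whose reads cannot be divided with certainty, so they are not separate evidence. A uniform fraction is argued against for these few genes only. A response whose size differs between genes as the EE effect weakens stays open, as does an action of the ligand on these genes. The real labels gave 218 called genes and the highest of the other splits 3. At 1 of 35 splits as large, the lowest these splits can give, chance is argued against for that count but not excluded.

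Macrophage, lymphocyte and proliferation genes rose with EE while hepatocyte genes fell; with an estimated correlation the list calls of the first 3 were lost (camera adjusted p = 0.29, 0.37 and 0.32) and that of secreted proteins held (0.031). A lower share of hepatocyte RNA as the only cause would raise the markers of other cells alike. Macrophage markers, however, rose by 1.68 ± 0.25 more than stellate markers (log2, mean per library, exact permutation p = 0.0286, the smallest that 4 against 4 allows). These lists had the largest and the smallest rise of the marker lists and were set against each other after the results were seen. The exact p does not allow for that choice and is no test here. Macrophage markers rose by 2.13, lymphocyte by 2.08, erythrocyte by 1.07, endothelial by 1.01, cholangiocyte by 0.97 and stellate by 0.45. Since all of these rose while secreted proteins changed by -1.36, a lower share of hepatocyte RNA stays open as part of the cause. Scaling between libraries as the whole cause is argued against by the secreted protein list, whose median was -0.88 with library totals against -1.36 here, but part of that size and the lymphocyte list call (adjusted p = 0.1 with library totals) rest on the scaling. More macrophages and lymphocytes, or a change within these cells, also stay open. The EE count exceeded that of every other split (6513 against 1, 1 of 35), and so did the difference of EM from CV (5251 against 1, 1 of 35).

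The genes raised by MI763F without EE include Dusp1, Gdf15 and G0s2. Without CM replicate 2 the median log2 fold change of the 12 called genes was 1.24 against 1.32, and all 12 lay more than 2 SE above 0. These genes were called with that library included, and a call favours genes that are alike between libraries, so this outcome was likely in advance. The folds of these 12 were thus similar without CM replicate 2, but whether that library drove the set stays open. With 1 library fewer 6 of the 12 stayed called, while Dusp1 (1.46 ± 0.28 against 1.54 ± 0.26), Gdf15 (1.67 ± 0.33 against 1.79 ± 0.31) and G0s2 (1.29 ± 0.24 against 1.26 ± 0.22) lost their calls at larger SEs and similar folds. Handling before sampling is consistent with the immediate-early genes, which rose together by 1.11 ± 0.34 (log2, 14 of 16 listed genes; exact permutation p = 0.0286, the smallest possible), although an effect of the ligand on them would look alike. Of 35 splits, 2 gave at least the 12 genes of the real labels and another gave 13, so chance cannot be excluded for this count.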

How the results depend on the processing

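Library totals and limma were chosen after seeing the data, and all other alternatives were planned; the cause of each change below was not tested. The total counts for EE (5868 to 6209 with 1 library left out, 6702 by DESeq2) and for EM vs CV (4543 to 4972, 5517 by DESeq2) stayed within 1.5 times under every alternative run. Their directions did not. With library totals EE gave 7048 up and 1329 down against 3291 and 3222, and 4730 of the 6513 genes stayed called. EM vs CV then gave 5979 up and 1000 down against 2668 and 2583, and 3675 of the 5251 stayed called. For MI763F without EE (12 genes) DESeq2 gave 238, only the groups compared 2, the replicate block 6, and leaving out 1 library 4 to 39. For MI763F in EE mice (195 up, 23 down) DESeq2 gave 487 up and 99 down, library totals 75 up and 52 down, only the groups compared 47 down, and leaving out 1 library 34 to 376 up and 2 to 69 down. For the interaction (17) DESeq2 gave 462, the replicate block 79, library totals 26, limma 30, and leaving out 1 library 10 to 208. The share of opposite sign (87.1%) ranged from 83.4% to 88.7% with 1 library left out; the genes called in that direction (215) numbered 125 with library totals, 29 with EV divided, and 36 to 438 with 1 library left out. The correlation of the ligand effects (-0.0283) ranged from -0.064 to 0.0322, and the genes raised in both (1) from 0 to 2. Of 72 list calls, an estimated correlation kept 3; fry called 56 (48 of them among the 72), the replicate block 72 and library totals 70 (68 among the 72). Library totals turned Abcc3 (0.05) and Abcb4 (0.01) around in EV vs CV. Called named genes kept with each library left out were 86 of 86 for EV vs CV, 1 of 6 for CM vs CV, 9 of 31 for EM vs EV, 14 of 14 for EM vs CV and 5 of 6 for the interaction. DESeq2 lost 1 of the 86 and 1 of the 14, Slc34a2 in both. The replicate numbers do not pair the samples. Of 24 same-numbered pairs 0 correlated above 0.1 (-0.052 to 0.096), and 6 of 24 matched best with their own number. A call lost under the block therefore need not mean a weaker effect. At this depth and with 4 libraries per group, 34.3% of simulated 2-fold differences were recovered for the interaction and 58.2% to 65.7% for the other comparisons.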

Other observations

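The comparisons were planned, while the choice of the Sult2a family and the tests of departure from a common fraction were made after the results were seen; the immediate-early list was fixed before its own values. The 8 tested members of the Sult2a family, sulfotransferases of steroids and bile acids, all fell with EE. In EE mice 6 of the 8 rose with MI763F, among them Sult2a2 (2.61) and Sult2a4 (2.55), and for 5 of the 8 the ligand effect differed from that without EE. The rise of Sult2a3 (2.96) lost its call in 7 of 8 fits with 1 library left out and under the replicate block. Near-identical sequences make the division of reads among these genes uncertain.

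The genes that departed from the common fraction moved back were of both kinds. Of these 18 among 6513 EE-changed genes, 13 had been lowered by EE and moved back further, such as Cyp2b10 by 95.2%. Cyp3a16 moved back by 175%, past its level without EE. It was low, at 2.23 ± 1.4 CPM in CV, 0.896 ± 0.35 in EV and 4.36 ± 1.1 in EM. The division of reads among Cyp3a genes is uncertain, so this return may not be its own. Of the 5 raised by EE, Krt79, Krt4, Trex2 and Asic2 moved back less and Ggct (1.81 with EE) lay 0.25 higher with the ligand instead of moving back. In all, 4 of the 18 had under 20 counts in CV or EV, so that their fold, and their fraction, rest on the floor. With a separate fraction for each direction (25.6% for lowered and 14.4% for raised genes), 13 genes departed, all 13 among the 18.

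The immediate-early genes averaged 3.34, 3.8, 4.57 and 4.32 log2 CPM in the CV libraries and 4.85, 5.71, 5.08 and 4.84 in the CM libraries. The difference of EV from CV was 0.18 and that of EM from EV 0.35.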
